A study of Rattus norvegicus with 6 samples.

How the data were processed

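Methylated DNA immunoprecipitation followed by hybridisation to tiling arrays (MeDIP-chip) was done on hearts of newborn Sprague-Dawley rats at day 1. Per the labels, 3 arrays held offspring of dams given saline (control), 3 held offspring of dams given a suspension of fine particulate matter (PM2.5) into the trachea, and each array carried immunoprecipitated DNA in Cy5 and its own input DNA in Cy3. The labels call the 3 samples of each group biological replicates. They do not say whether pups came from separate litters, so the p-values measure the spread between these samples. The PM2.5 dose and the sex of the pups are not given in the sources used here.

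Spot intensities were deposited as scanner output of Feature Extraction 11.0.1.1; per the file headers the processed intensity of each channel was background-subtracted, spatially detrended and dye-normalised by a linear factor, and low signals were replaced by a surrogate. Each array held 172669 probes of 45 to 60 nt, 1 spot each, with coordinates on the rat build rn4 per the file headers. The table of log2 values that the authors deposited was used as an alternative. Its array medians lay between -0.006 and 0.027, its values correlated at 0.787 to 0.854 with the log2 ratio of the same array, and neighbouring probes correlated at 0.753 to 0.81 in it against 0.235 to 0.337 in the scanner ratios. Its direction follows MeDIP over input, while its scale and smoothing remain unknown.

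The log2 ratio of Cy5 over Cy3 processed signals was computed per probe in R 4.3.3 with the package data.table (version 1.17.8). Control spots and spots marked as uneven or as population outliers were left out, and a probe was kept where its input was well above background on all 6 arrays, which held for 135720 probes. Each array was centred on the median of its own remaining probes. This centring, the tests, the filters and most alternatives were fixed before the data were examined. On PM2.5 replicate 1, 35.8% of spots were marked, against 0.34% to 2.21% on the other arrays, so its centre rests on another set of probes. Centring on the probes unmarked on all arrays, centring on all kept probes, and keeping marked spots in both values and centre were tried after seeing the data. The first of these was for a time used in place of the centring fixed beforehand, with the counts of each already known, and was returned to an alternative so that the choice would not follow the counts. The calls under each stand beside the lead count of regions.

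The files pair no probe with a gene, and the annotation at hand is of another build, so the planned tests of gene promoters, gene lists and genes chosen for naming were not analysed here. In their place, a choice made after the files were seen, probes separated by gaps of at most 1000 bp were joined into 16123 tiled regions, with a median of 10 probes and 1664 bp. The mean ratio of probes unmarked on all 6 arrays was tested in the 14786 regions with at least 2 such probes. A region's median number of such probes was 4.

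Probes and regions were tested with lmFit and eBayes of limma 3.58.1 as PM2.5 minus control, with Benjamini-Hochberg adjusted p under 0.05. Runs were at least 3 neighbouring tested probes with gaps of at most 1000 bp, each with an unadjusted p under 0.05 and one sign. Regions named were the 10 largest rises and 10 largest falls past the threshold with groups that did not overlap, filled where fewer passed by the smallest unadjusted p among regions with at least 3 probes. The 5 runs with most probes per direction, with ties broken by the mean absolute t, were also named. Values per array were compared by two-sided exact permutation tests, which with 3 arrays against 3 cannot give a p below 0.1. The number of arrays limits the precision.

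Data were simulated with the spread of the real regions, each region independent of the others and without shifts shared by an array. Among 14786 such regions the test recovered 65 of 100 changes of 1 on the log2 scale. It recovered 6 of 100 changes of 0.5, with 0 false calls. No other simulated regions were changed, whereas 4897 real regions had an unadjusted limma p under 0.05. Recovery at an adjusted p depends on how many regions change. Real regions can also shift together on an array, so these rates need not carry over to them. Alternatives covered background correction (normexp with an offset of 50 on median signals, since the files used hold no mean spot signal), scale, quantile and loess normalisation (span 0.3), filters, blocks for replicate number, scanning day and slide, each array left out, other variance models and array weights. Centring each probe length by itself was added after seeing the data. The correlation within the slide shared by controls 2 and 3 was a moment estimate of 0.574, because duplicateCorrelation returned none; the tests as designed treat these arrays as independent. Figures were drawn with matplotlib 3.10.9.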

Results

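The series asked how exposure of pregnant rats to PM2.5, airborne particles of small diameter, relates to DNA methylation in the heart of their newborn offspring. Enrichment was read as the log2 ratio of immunoprecipitated over input DNA, centred on each array's own median. A higher ratio at the same probes was read as more methylated DNA captured relative to the input and to that median. Where Cy5 was not well above background, a higher ratio cannot be read in this way. There were 3 control and 3 PM2.5 arrays. Input signal was well above background at 83.5% to 90.4% of probes on control arrays and at 83.0% to 87.3% on PM2.5 arrays. The median input spot was 3.83 to 18.4 times its local background over the 6 arrays.

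The ratios had a smaller standard deviation on the PM2.5 arrays. The standard deviation over probes was 1.30 ± 0.0637 in controls and 1.04 ± 0.0412 in PM2.5 (mean ± SD, n = 3 each), and each PM2.5 array lay below each control array (exact two-sided permutation p = 0.1, the smallest that 3 against 3 can give). Over tiled regions it was 0.794 ± 0.0469 in controls and 0.63 ± 0.0145 in PM2.5 (n = 3 each). Probes with a log2 ratio under -1 made up 31.7% ± 2.91 of control and 22.6% ± 1.8 of PM2.5 values (SD, n = 3 each; exact permutation p = 0.1). Those above 1 made up 5.55% ± 1.38 and 5.62% ± 5.84 (SD, n = 3 each; exact permutation p = 1). The PM2.5 mean rests on replicate 1 with 12.35%, and without it was 2.25%, with both other PM2.5 arrays below each control array. The difference in standard deviation between groups was -0.255, and -0.12 after normexp correction. In the authors' values the groups overlapped, with 0.638, 0.654 and 0.656 in controls and 0.589, 0.639 and 0.64 in PM2.5. Within the scanning day that held 1 array of each group the region spread was 0.744 in the control and 0.615 in PM2.5, and within the day that held 2 controls and 1 PM2.5 array it was 0.819 and 0.63. PM2.5 replicate 1 was scanned alone on another day.

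Comparing offspring of exposed and unexposed dams, 1447 of 14786 tiled regions had a higher ratio in PM2.5 and 7 a lower one (limma, adjusted p under 0.05). The rises had a median of 0.67 on the log2 scale and ranged from 0.45 to 1.52. They lay in regions of low ratio, with a median of -1.66 in controls and -0.96 in PM2.5. The 7 falls lay in regions of high ratio, from a median of 1.02 in controls to 0.47 in PM2.5. The mean probe length of regions had a median of 51.33 nt in the rises, 45.11 nt in the falls and 48.4 nt over all. The level of the ratio differs with probe length, so levels of different regions are not read as amounts of captured DNA. Both directions moved towards the middle of the range. The median change over all tested regions was 0.24 under this centring and 0.000744 in the authors' values. It was 0.136 without PM2.5 replicate 1 and 0.132 with the scanning day as a block, which also sets that array aside. It lay between 0.0589 and 0.152 with normexp, scale, quantile, loess, probe-length centring, marked spots kept or both channels well above background. It was 0.0501 when each array was centred on the probes unmarked on all arrays, where 320 regions were higher and 32 lower. A centre moves all regions of an array alike, so this centring lowered the change of each region by the same amount. The 1447 rises and 7 falls were counted without that lowering, and which centre is right was not tested. Centring on all kept probes gave 2148 higher and 34 lower, and keeping marked spots 1159 higher and 40 lower. In limma, 0 regions passed after scale normalisation (1167 higher and 47 lower at an unadjusted p under 0.05), quantile normalisation (1157 and 140), normexp correction (2845 and 145) or centring of each probe length (2070 and 473), in the authors' values (575 and 420), or without control replicate 3 (2685 and 23). Within-array loess gave 334 higher and 51 lower. Without control replicate 2 there was 1 region past the threshold, without PM2.5 replicate 1 there were 1734, and with the slide shared by controls 2 and 3 as a random block 9 were higher and 0 lower.

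**Figure D1:**
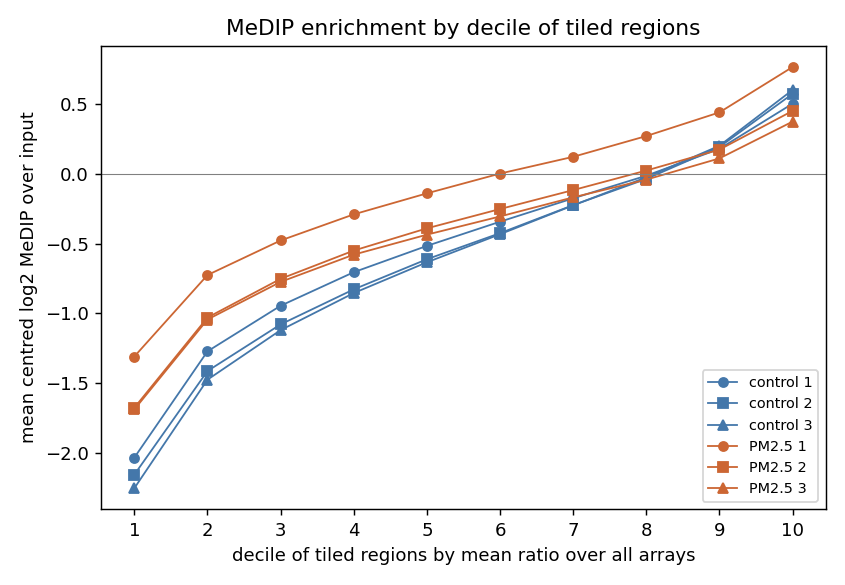
Mean centred log2 ratio (vertical axis) of tiled regions sorted into deciles by their mean over all 6 arrays (horizontal axis), with 1 line per array, blue for control and orange for PM2.5. In the lowest decile control arrays lie between -2.25 and -2.03 and PM2.5 arrays between -1.69 and -1.31.

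By level, the lowest decile of regions held 675 of the rises and a median change of 0.58, while the highest decile held 0 rises, 5 falls and a median change of -0.02, whose sign turned without PM2.5 replicate 2 (0.01) or PM2.5 replicate 3 (0.05). Among the 4928 regions of lowest ratio, the mean was -1.46 ± 0.099 in controls (SD, n = 3) and lay between -1.12 and -0.79 on the PM2.5 arrays (exact permutation p = 0.1). The median change of these regions was 0.45, and 98.3% of them had a higher mean in PM2.5. Their median change was 0.26 with the common centring (90.1% higher), 0.25 with scale normalisation (90.4%), 0.18 with quantile normalisation (82.8%) and 0.04 in the authors' values (64.7%). The exact permutation p of their mean was 0.4 with scale normalisation, 0.2 with quantile normalisation and 0.3 in the authors' values, and 0.1 in the 7 other scalings and filters tried. At probes well above background in both channels, 4402 of these regions had a median change of 0.21 against 0.44 over all probes used, and with the common centring 0.02 against 0.25. Among the 4929 regions of highest ratio the mean was 0.20 ± 0.0141 in controls and 0.26 ± 0.18 in PM2.5 (SD, n = 3 each; exact permutation p = 1), and without PM2.5 replicate 1 the PM2.5 mean was 0.15, below that of controls. The sign of their median change differed between settings, at 0.06 as designed, -0.05 without PM2.5 replicate 1 and -0.13 with the common centring. Probes of 60 nt, the longest, had a mean ratio of -1.93 ± 0.129 in controls and -1.34 ± 0.176 in PM2.5, and those of 45 nt 0.0882 ± 0.0337 and 0.119 ± 0.181 (SD, n = 3 each; exact permutation p = 0.1 and 0.9). Without PM2.5 replicate 1 the PM2.5 mean of the 45 nt probes was 0.0168, below that of controls. The gap between 45 nt and 60 nt probes was 2.02 ± 0.162 in controls and 1.46 ± 0.0414 in PM2.5. The gap between X and autosomal probes was -0.142 ± 0.0462 and -0.083 ± 0.107 (exact permutation p = 0.5), and without PM2.5 replicate 2 it was -0.144 in PM2.5 against -0.142.

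First by the naming rule among the rises was a region on chromosome 20 from 5140243 to 5141402, where the ratio was -3.20 ± 0.427 in controls and -1.68 ± 0.0894 in PM2.5 (SD, n = 3 each), a change of 1.52 with a standard error of 0.195 and a limma adjusted p of 0.0194. The next was on chromosome 1 from 86329445 to 86331098, with -2.74 ± 0.113 in controls and -1.25 ± 0.433 in PM2.5 and an adjusted p of 0.0194. On chromosome 3 from 58928229 to 58929970 the ratio was -2.25 ± 0.236 and -0.85 ± 0.498, and on an unplaced sequence from 34001258 to 34002289 it was -3.05 ± 0.0657 and -1.66 ± 0.502. The 10 named rises ranged from 1.25 to 1.52, with adjusted p from 0.0194 to 0.0262. They rest on 2 to 4 probes used each. With the slide as a random block 3 of them passed, with adjusted p from 0.0349 to 0.0659 (limma). At 10 of these 10, at least 1 probe used had Cy5 not well above background on any control array, so their sizes and order rest partly on signals near background. They ranged from 0.46 to 0.81 with normexp, from 0.71 to 1.03 with quantile normalisation, from 0.20 to 1.17 with marked spots kept and from 0.01 to 0.46 in the authors' values. At 4 of these 10, on chromosomes 1 (from 216137282), 14 (from 18691633), 8 (from 63189445) and 6 (from 85797978), no probe used had Cy5 well above background on any PM2.5 array, and at 3 of them on no array of either group, so no fold is given. Among the 1447 rises, 35 regions had no probe with Cy5 well above background in either group. With both channels well above background on all 6 arrays, 22 of 11776 regions were higher and 0 lower (limma; 1896 and 391 at an unadjusted p under 0.05).

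The largest fall was on chromosome 12 from 42696398 to 42696743, from 1.09 ± 0.0905 in controls to 0.31 ± 0.209 in PM2.5 (SD, n = 3 each), with a standard error of 0.148 and an adjusted p of 0.0252. On chromosome 5 from 153291494 to 153293203 the ratio was 0.31 ± 0.223 in controls and -0.39 ± 0.164 in PM2.5. Chromosome 15 held 2 of the 7 falls, from 33968487 to 33970088 with 1.16 ± 0.212 and 0.56 ± 0.158, and from 82827923 to 82829598 with 1.08 ± 0.161 and 0.51 ± 0.135. The remaining falls were on chromosome 3 from 103184124 to 103184693 and on chromosome 1 from 219520656 to 219521452 and from 209643207 to 209644822. All probes used in these 7 regions had Cy5 well above background on at least 1 array of each group. Each region rests on 2 or 3 probes used. With at least 5 probes required none of the 7 was tested, and 0 of 5508 regions were lower. The 7 falls ranged from -0.785 to -0.492, from -0.888 to -0.226 without a filter, from -0.63 to -0.218 with marked spots kept and from -0.531 to -0.103 in the authors' values. With the slide as a random block 0 of the 7 passed, with limma adjusted p from 0.0616 to 0.11, and with both channels well above background 0 of the 6 tested did, with 0.0581 to 0.0888. With loess, without a filter, with region medians and with trend and robust estimation, 2 of the 7 passed in each. A further 3 regions, on chromosomes 9, 20 and 6, filled the list and did not pass, with adjusted p from 0.0624 to 0.0728. No gene is named for any region.

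**Figure D2:**
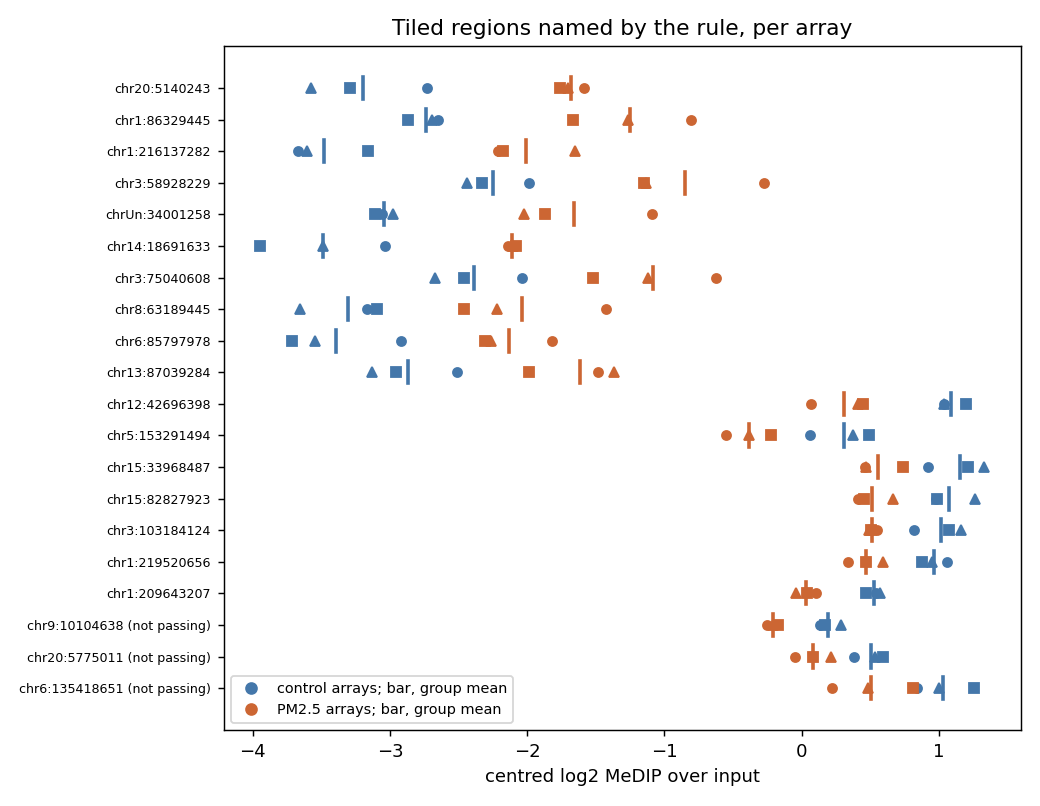
Centred log2 ratio (horizontal axis) of the 20 tiled regions chosen by the naming rule (vertical axis, chromosome and start on rn4), with 1 marker per array and a bar at each group's mean, blue for control and orange for PM2.5. At the first region control arrays lie between -3.57 and -2.73 and PM2.5 arrays between -1.76 and -1.58, and the last 3 regions did not pass the threshold.

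Probes marked on some arrays entered the tests of single probes and runs without those arrays, unlike in the regions. Of the 135720 kept probes, 70843 were unmarked on all arrays. Of single probes, 1761 of 135548 were higher and 8 lower in PM2.5 (limma, adjusted p under 0.05). The common centring gave 878 and 34, and 0 probes passed without control replicate 2, control replicate 3, PM2.5 replicate 2 or PM2.5 replicate 3 (13474, 12478, 19327 and 20142 higher, and 1574, 1396, 4136 and 4113 lower, at an unadjusted p under 0.05). Without PM2.5 replicate 1, 3436 were higher and 103 lower. In limma, 0 probes also passed after normexp correction, scale or quantile normalisation, centring of each probe length, trend and robust estimation, or in the authors' values (14620, 10057, 9060, 12506, 18368 and 7207 higher, and 4655, 2763, 3941, 7304, 4934 and 4313 lower, at an unadjusted p under 0.05). Runs of neighbouring probes numbered 752, of which 742 were higher and 10 lower. The longest held 8 probes, on the X chromosome from 140034910 to 140036836 with a ratio of -2.13 ± 0.193 in controls and -1.07 ± 0.308 in PM2.5, and on an unplaced sequence from 426940 to 428191, where the mean of the probe changes was 0.97. A further 3 of the longest runs were on chromosome 1, starting at 116086980, 116177155 and 116210828, with mean changes of 1.13, 0.777 and 1.01. The tiled region that holds the X run did not pass, with a change of 0.341 and a limma adjusted p of 0.106. Neither did the region of the chromosome 1 run from 116086980. The 5 named runs of rises ranged from 0.777 to 1.13, from 0.322 to 0.848 with scale normalisation, from 0.231 to 0.708 with quantile normalisation and from 0.035 to 0.573 in the authors' values. The longest run of falls held 4 probes on chromosome 15 from 82828859 to 82829428, with 1.04 ± 0.126 in controls and 0.465 ± 0.0767 in PM2.5. There were 99 runs after scale normalisation, 71 after quantile normalisation and 156 with both channels well above background. With the common centring there were 297 runs higher and 112 lower, without control replicate 2 there were 331 in all, and without control replicate 3 there were 254.

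Within scanning days, the 4928 regions of lowest ratio had a median change of 0.23 on the day with 1 array of each group, where 85.2% were higher in PM2.5, and of 0.41 on the day with 2 controls and 1 PM2.5 array, where 95.7% were. Over all 14786 regions it was 0.06 and 0.19. With the day as a block, 2537 regions were higher and 124 lower. PM2.5 replicate 1, alone on its day, adds nothing to that contrast, which rests on the days above. The spread in that fit comes partly from controls 2 and 3, which were scanned on 1 day and share a slide. The variance over regions was 0.0136 within that slide against 0.032 between controls across slides. The counts with the day as a block may therefore be too high.

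**Figure D3:**
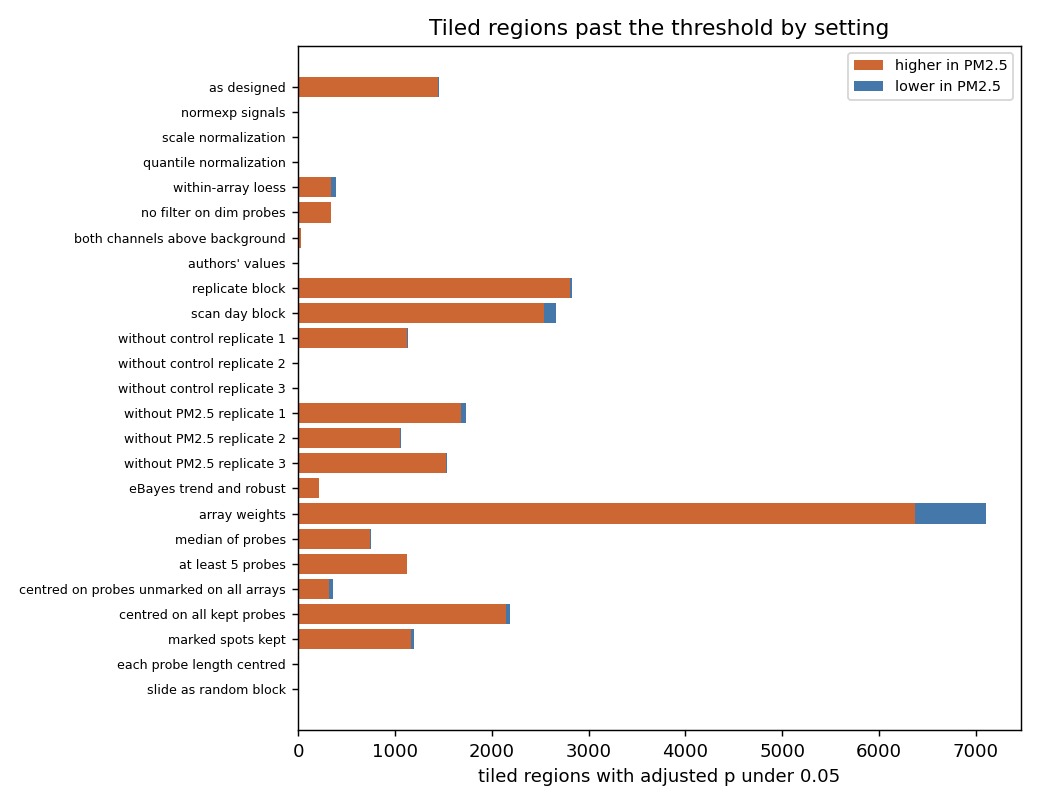
Number of tiled regions past an adjusted p of 0.05 (horizontal axis) under each setting (vertical axis), orange for higher and blue for lower in PM2.5. The bar as designed holds 1447 and 7, and several settings hold 0.

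Between arrays, PM2.5 replicate 1 correlated with the others at 0.83 to 0.848 over probes, and the remaining 10 pairs at 0.904 to 0.975. The first principal component of the regions held 70.5% of the variance, with controls between -28.4 and -10.8 and PM2.5 arrays at 49.5, 7.93 and 5.89. Shifts of a whole array, which depend on its centring, were left in the regions. PM2.5 replicate 1 had the highest mean in both the lowest and the highest decile (-1.31 and 0.76). The component therefore does not separate such shifts from differences in pattern. The highest correlation was between controls 2 and 3, which shared a slide. On probes well above background in both channels, this pair differed by a standard deviation of 0.178 per array.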

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

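Other centrings, marked spots kept, probe-length centring, the slide block and the alternatives for correlations were chosen after seeing the data. Causes of the changes from 1454 regions, 1769 probes and 752 runs were not tested. For the centrings, part of the change follows from the calculation. Centring on the probes unmarked on all arrays lowered the change of each region by the same amount. The first named rise went from 1.52 to 1.33 and the first named fall from -0.785 to -0.972. Regions, probes and runs were 0, 0 and 355 with normexp, 0, 0 and 99 with scale normalisation, 0, 0 and 71 with quantile normalisation, 385, 1067 and 470 with loess, 22, 0 and 156 with both channels above background, and 0, 0 and 179 with each probe length centred. Regions with an unadjusted p under 0.05 were 2845 higher with normexp, 1167 with scale, 1157 with quantile and 2070 with length centring (limma). Without a filter 341 regions and 1 probe passed with 791 runs, and in the authors' values 0 and 0 with 591 runs, of which 401 were higher and 190 lower, against 742 and 10. Neighbouring probes correlated at 0.753 to 0.81 in the authors' values against 0.235 to 0.337 in the scanner ratios. Correlated neighbours form runs more readily, and 172669 probes were tested there against 135548. The 2 sets of run counts are therefore not alike. Centring on probes unmarked on all arrays gave 352, 912 and 409 (90.9% of regions and 72.6% of runs higher, against 99.5% and 98.7%), and on all kept probes 2182 regions. With trend and robust estimation 214 regions and 0 probes passed, with array weights 7107, 19752 and 1648, with region medians 747 and with the slide block 9. Runs of at least 2 or 5 probes numbered 3297 and 41, and 122 at a probe p under 0.01. The scanning-day block, which sets PM2.5 replicate 1 aside as the only array of its day, gave 2661 regions and 7257 probes. Its spread comes partly from controls 2 and 3, which share a slide, so these 2 counts may be too high. The replicate-number block gave 2825 regions and 5679 probes. Deviations from the group mean correlated between same-numbered arrays at -0.0081, 0.11 and -0.15. With so few arrays, these values cannot tell whether the numbers pair the samples. Leaving out 1 array gave 0 to 1734 regions, 0 to 3539 probes and 254 to 866 runs. No named region changed sign in an alternative that tested it, but not every alternative tested them all. With both channels above background 9 of the 20 were tested, none of them a rise. The named regions rest on 2 to 4 probes used, so with at least 5 probes required none of the 20 was tested. In that setting 1120 of 5508 regions were higher and 0 lower (limma, adjusted p under 0.05). Of the 17 named calls, 17 had a limma adjusted p above 0.05 with scale, quantile, normexp, length centring or the authors' values. The same held without control replicate 3. Of 104 values of named runs of rises under alternatives 30 moved, and of 105 of falls 13, with no change of sign. With the slide block 14 of the 17 named calls were lost. The difference in spread between groups was -0.12 with normexp against -0.255, and in the authors' values the spreads of the groups overlapped. The group difference in the gap of 45 nt to 60 nt probes was -0.242 with normexp against -0.561. The mean correlation of PM2.5 replicate 1 with the others was 0.838, and 0.814 with marked spots kept, 0.78 with normexp and 0.794 in the authors' values. Alternatives for gene lists and gene promoters were not run. At least 1 probe used had Cy5 not well above background on any control array in 1212 of 1447 rises (83.8%) and in 6465 of all 14786 regions tested (43.7%), so levels there rest partly on signals near background.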

Other observations

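The chromosome classes and the tests of spread, probe length, uneven spots, scanning day and X input below were chosen after the result was seen, as were the splits of regions and probes; the bright-probe test and the splits of runs were set before, while checks of the bright-probe value without each array, with another centring and on regions taken whatever their call were added after it was seen.

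Long tiled stretches were a class picked after the values were seen. All 89 tested stretches of more than 100 probes had a higher mean in PM2.5 as designed, as did 83.6% of all regions tested. The median change was 0.33 in the stretches against 0.24. The stretches hold more probes and had a lower median control ratio (-0.802 against -0.49), so length is not separated from probe number or ratio level. The threshold was passed by 7 (limma), 7.87% against 9.83% of all regions. With the common centring 77 were higher (86.5% against 57.7% of all regions) and 1 passed, with quantile normalisation 88 (98.9% against 73.6%) and 0, and in the authors' values 71 (79.8% against 50.3%) and 0. The 2 stretches with the largest change were neighbours on chromosome 5. From 53440004 to 53468735 the ratio was -1.6 ± 0.127 in controls and -0.89 ± 0.198 in PM2.5. From 53481662 to 53504857 it was -1.6 ± 0.19 and -0.96 ± 0.132 (SD, n = 3 each). With 22 chromosome classes tested by Fisher's exact test, which treats regions as independent, calls made up 3.07% of regions on chromosome 19 against 10% elsewhere (adjusted p = 3.02e-05) and 13.9% on X against 9.69% (adjusted p = 0.0217). Chromosomes 7 and 10 also had fewer, at 7.24% against 10% (adjusted p = 0.0238) and 6.77% against 10.1% (adjusted p = 0.00128). With the common centring chromosome 7 alone had an adjusted p under 0.05 (0.931% against 2.48%, adjusted p = 0.0214), and chromosomes 19, X and 10 had 0.562, 0.562 and 0.727. As designed, 1268 of the 1447 rises lay in the 4928 regions of lowest ratio. X probes had a lower mean ratio in controls than autosomal probes (-0.768 against -0.626). Chromosome is therefore not separated from ratio level in these shares.

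The rises in regions of low ratio have several open explanations, maternal exposure among them as untested. Dividing each array by its spread took the median change of the called rises from 0.669 to 0.464 and the median of the single regions' limma standard errors from 0.16 to 0.209, and 0 calls were left. Centring each probe length, which may stand in for base composition, took the median change to 0.39, again with 0 calls. The median of those standard errors became 0.131. In both the change shrank but kept its sign. These regions were chosen as rises on the same arrays, so the kept sign does not weigh on either explanation, and both remain open. On probes well above background in both channels the median change in 1222 called rises was 0.409 against 0.652 over all probes used, a share of 0.627 and above the bound of 0.5 set beforehand, but those probes had helped to make the calls; in 4402 regions of low ratio taken whatever their call the share was 0.469 (0.372 without PM2.5 replicate 1 and 0.537 without PM2.5 replicate 3), and 0.0735 with the common centring, so dim Cy5 signal remains open. The 10 splits of the 6 arrays are too few for a share under 0.05. Only the real split, 1 of 10, gave as many calls, with 1454 regions, 1769 probes and 752 runs. The others gave 0 regions, 0 probes and at most 68 runs. At an unadjusted limma p under 0.05 the real split gave 4897 regions. Other splits that kept controls 2 and 3, which share a slide, together gave 414 to 1022, and those that parted them 26 to 211.

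PM2.5 replicate 1 stood apart from the other arrays. On probes unmarked on all arrays its highest correlation with another was 0.848, under the lowest of the other pairs at 0.904, which argues against the marked uneven spots as the whole cause. Its scanning day held 1 array, so the day and the sample cannot be told apart. A difference between animals was not tested.

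The X input signal differed between arrays. Matched on probe length and signal, it ranged over 0.12 on the log2 scale, against at most 0.045 on an autosome, which argues against a mismatch of probe length or signal level. The immunoprecipitated X signal ranged over 0.048, against at most 0.047 on an autosome, so X did not stand apart there. The sex of the animals may contribute, but the labels do not give it, and the 3 arrays with low X input are those of 1 scanning day, so sex and day cannot be told apart.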
